A study of Homo sapiens with 9 samples.

How the data were processed

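RNA was sequenced from cultures of the A549 human lung adenocarcinoma cell line in 9 libraries, 3 for each of 3 groups. The groups were vehicle (DMSO), the GPX4 inhibitor RSL3 at 2 µM, and RSL3 at 2 µM together with ferrostatin-1 (Fer-1) at 5 µM, each for 24 h. The starting material was total RNA, and the series covers messenger and long noncoding RNA. Replicate numbers come from the sample names. The labels do not say whether the 3 libraries of a group came from separate cultures, so every p-value measures the spread between these samples only. They also do not say whether the libraries were stranded, so a locus that overlaps another may hold reads of its neighbour.

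The deposited table holds 43444 loci with an estimated count and an FPKM per library, per the file headers. Reads were trimmed with cutadapt 1.9 and inspected with FastQC, and the genome build is GRCh38, per the submitters' processing notes. The aligner, the assembler and the program that counted reads are not given in the sources used here. Most locus identifiers start with MSTRG, the prefix that StringTie gives to assembled loci. The deposited counts are whole numbers without scaling for depth or length, per the file headers and the values. In 5599 loci with a single transcript and no strand, 96.9% of the counts equal FPKM times transcript length times 1 constant per library, rounded up, within a tolerance of 0.05 counts. FPKM computed from tallies of reads would hold to that relation as well. It therefore does not settle whether the counts are tallies or estimates from coverage. They are called estimated counts here. The deposited FPKM values, per the file headers, are scaled by the authors for transcript length and library depth.

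Coordinates are those of the table, on GRCh38. Of 10028 loci that carry an Ensembl identifier, 9592 are in GENCODE 29, and 68.8% of these have identical start and end positions there while 82.7% lie within the annotated gene. Loci without a gene name numbered 1496 and took 0.48 to 0.546% of the counts of a library. They were left out of the library sizes and of the main tests, which left 41948 named loci. The names of 2501 loci join 2 or more genes, and these loci took 32.2 to 32.9% of the counts. A value given for a gene in such a locus is that of the whole locus. Loci were classed as long noncoding when their transcript types included long noncoding RNA and no coding, decay or ribosomal type. No locus of the table lies outside chromosomes 1 to 22, X and Y, so the list of mitochondrially encoded genes had 0 measured members.

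Counts were normalised with TMM factors, which lay between 0.991 and 1.01, and tested with edgeR 4.0.16 in R 4.3.3. Loci with an FPKM of at least 1 in at least 3 of the 9 libraries were tested, 17297 in all. One quasi-likelihood model with robust dispersion was fitted to all 9 libraries and 3 groups, and each comparison was a contrast of that model. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a locus was called at an adjusted p under 0.05. Levels are CPM, counts scaled by library total and by these factors, given as mean ± SD with n = 3. Log2 changes of loci are those of the edgeR fit with its default prior count, and their SE was derived from the quasi-likelihood F statistic. A prior count of 2 was used in the log2 CPM behind the part of a change that remained with Fer-1. The same log2 CPM gave the list means per library. The plan named limma on log2(FPKM + 1) for a table of FPKM alone and edgeR for a table of raw counts. Since the table has whole-number counts per library, edgeR was used, and limma was run as an alternative. Whether these are raw counts is not settled, so it is open which test the plan called for. The choice of edgeR was made with the table in view. Limma on log2(FPKM + 1) called fewer loci in every comparison, 2058 against 2854 for RSL3 against DMSO.

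Library totals ran from 39143521 to 45855255 estimated counts, so a count of 0 in a library allows up to 3 counts, or 0.0658 to 0.077 CPM. Such floors cover counting error only. On simulated counts drawn from the real means and library sizes, the same test recovered 46%, 50% and 56% of changes of 0.5 on the log2 scale for RSL3 against DMSO, RSL3 plus Fer-1 against RSL3, and RSL3 plus Fer-1 against DMSO. It recovered 79%, 78% and 76% of changes of 1 on the log2 scale in the same order, and 4.6%, 9.2% and 8.3% of the calls were false.

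The 30 gene lists covered regulators and markers of ferroptosis, stress and signalling responses, metabolism, cell division, and markers of other cell types. Camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 tested the 25 lists with at least 5 tested members, with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry were run beside it. In other splits of the same libraries the preset correlation gave calls in up to 13 lists, so a list call that rests on it alone is weak. For each list the text also gives the number of members called when p-values are adjusted over the list alone.

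Genes are named by a rule. In each comparison these are the 6 largest rises and 6 largest falls among called genes with a mean FPKM of at least 5 in the higher group and no overlap between the libraries of both groups. Added to them are the 3 most changed called members of each list that passes the camera test, and the 3 largest rises and 3 largest falls among called long noncoding RNAs with a mean FPKM of at least 1 in the higher group. A further 12 genes of ferroptosis biology are always named, namely GPX4, SLC7A11, CHAC1, PTGS2, HMOX1, TFRC, ACSL4, AIFM2, FTH1, ATF3, DDIT3 and TXNRD1. CHAC1 and ATF3 did not reach the FPKM minimum, and their values come from the fit with the filterByExpr filter. Some genes that the rule names are not reported here. A gene named outside the rule is said to have been chosen after its values were seen.

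The part of the RSL3 change that remained with Fer-1 was estimated as a slope across all tested loci. The covariance and variance in it were corrected for the noise of the shared DMSO libraries, and its SE is a jackknife over libraries. Overlaps between comparisons that share a group were set beside the number expected of independent lists and beside 20 simulations of unchanged groups. The grouping, the comparisons, the candidate tests, the gene lists, the rule for named genes and most alternatives were set before the data were examined. The choice between edgeR and limma as the main test was made after the table was seen.

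The alternatives were another normalisation (DESeq2 1.42.0, quantile, RLE), other filters on low values, other pseudocounts, limma on FPKM, library weights, a model without trend and robust estimation, a replicate block, the 6 libraries of a comparison alone, loci of a single annotated gene, a minimum fold, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9.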

Results

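A549 cells, a lung adenocarcinoma line with a KEAP1 mutation and high NRF2 activity, were profiled by RNA sequencing after 24 h with DMSO, with 2 µM RSL3, or with 2 µM RSL3 and 5 µM Fer-1. RSL3 inactivates the lipid peroxidase GPX4 and thereby triggers ferroptosis, and Fer-1 traps lipid radicals and blocks that form of cell death. Each group had 3 libraries. The estimated counts per library summed to 43393109, 40549601 and 42777617 with DMSO and to 40500610, 40693436 and 39143521 with RSL3. With RSL3 plus Fer-1 they summed to 43815904, 45491371 and 45855255. Protein-coding loci took 80.7 to 81.9% of the counts and long noncoding RNA loci 8.19 to 8.78%.

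RSL3 against DMSO asks how A549 cells respond to GPX4 inhibition. The largest rise among well-expressed genes was in CXCL8, the neutrophil chemokine interleukin-8, from 3.57 ± 0.825 to 51.8 ± 9.32 CPM (SD, n = 3), or 14.5-fold. The cytokine IL11 rose from 8.99 ± 0.79 to 48.3 ± 2.05 CPM, and the stress hormone GDF15 rose from 2.97 ± 1.17 to 13.6 ± 2.41 CPM. The aldo-keto reductases AKR1C2 and AKR1C3, which detoxify reactive carbonyls, rose 6.36-fold and 4.56-fold. SLC7A11, the cystine transporter that feeds glutathione synthesis, rose from 439 ± 15.6 to 1040 ± 59.2 CPM, or 2.37-fold. The scavenger receptor OLR1 fell from 31.2 ± 2.72 to 14 ± 2.25 CPM.

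In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, CXCL8 rose by 3.86 on the log2 scale (SE 0.157, adjusted p = 7.51e-11), IL11 by 2.42 (SE 0.0955, adjusted p = 2.91e-16) and GDF15 by 2.19 (SE 0.227, adjusted p = 5.75e-07). The hypoxia-responsive carbonic anhydrase CA9 rose from 3.81 ± 1.08 to 23.4 ± 12.5 CPM (adjusted p = 0.0199). That call ended without any 1 of DMSO replicates 1, 2 or 3 or RSL3 replicates 1 or 3, with adjusted p values from 0.0519 to 0.0774. Other large falls were in the imprinted gene PEG10, 1.69-fold, in TENT5A, 1.62-fold, in the insulin-like growth factor binding protein IGFBP3, 1.58-fold, and in the zinc transporter SLC39A10, 1.54-fold. CXCL8 lies on chromosome 4 at 73740541 to 73742330 and SLC7A11 on the same chromosome at 138160486 to 138252227.

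**Figure D1:**
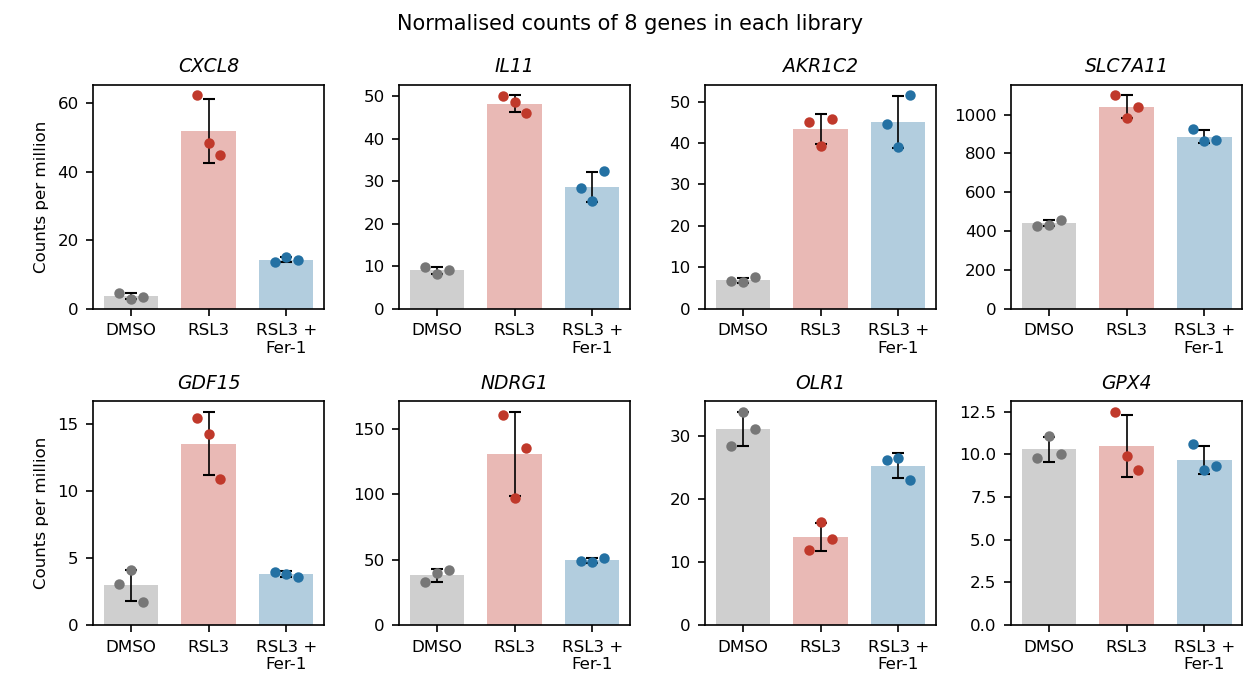
Normalised counts of 8 genes in CPM (vertical axes from 0) in each library by group, with bars for the group mean, error bars for the SD and points for the 3 libraries. CXCL8 averaged 3.57, 51.8 and 14.3 CPM with DMSO, RSL3 and RSL3 plus Fer-1, while AKR1C2 averaged 6.82, 43.4 and 45.1 CPM.

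GPX4 itself stood at 10.3 ± 0.7 CPM with DMSO and 10.5 ± 1.81 CPM with RSL3, a difference of 0.03 on the log2 scale (SE 0.14, adjusted p = 0.931) that was -0.01 under quantile normalisation or without DMSO replicate 1 and -0.12 without RSL3 replicate 1. The GPX4 locus, on chromosome 19 at 1103926 to 1106791, held 419 to 442 counts per DMSO library. That is few for a gene that is usually abundant in A549 cells. Whether short transcripts were under-recovered was not tested, so the level may be too low and the comparison may rest on part of the GPX4 transcripts. Of all protein-coding loci 24.9% were called with RSL3, a share to set beside the list counts that follow. Among ferroptosis suppressors 7 of 18 rose, 1 fell and 10 did not pass, and adjusted over the list alone 7 rose and 2 fell (camera adjusted p = 3.24e-08, adjusted p = 0.00497 with an estimated correlation). Risers included SLC7A11, the ferritin heavy chain FTH1, from 556 ± 20 to 1040 ± 82.3 CPM, and the thioredoxin reductase TXNRD1, 1.51-fold. All of these also stand in the list of NRF2 targets, as do the suppressors GCLC and GCLM, so the lists are not independent. AIFM2, which encodes the ubiquinone reductase FSP1, rose 1.23-fold (adjusted p = 0.0232), and that call ended without DMSO replicates 1, 2 or 3 or RSL3 replicates 1 or 3, with adjusted p up to 0.112. Ferroptosis drivers had 3 risers of 12 and 0 falls, and 4 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.0357, adjusted p = 0.107 with an estimated correlation). They were the polyamine acetyltransferase SAT1, 2.25-fold, the oxidoreductase POR, 1.25-fold, and CYB5R1, 1.25-fold, whose call ended without DMSO replicates 2 or 3 or RSL3 replicates 1 or 2 (adjusted p up to 0.101). ACSL4, which activates polyunsaturated fatty acids, and the transferrin receptor TFRC differed by 0.10 and 0.06 on the log2 scale (adjusted p = 0.0693 and 0.149).

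Response markers of ferroptosis rose in 5 of 9 tested members, 0 fell, and 8 rose adjusted over the list alone (camera adjusted p = 1.62e-11, adjusted p = 0.00973 with an estimated correlation). PTGS2, the inducible cyclooxygenase, rose from 7.28 ± 0.557 to 16.3 ± 2.53 CPM, haem oxygenase HMOX1 from 12 ± 2.65 to 23.1 ± 3.25 CPM, and the stress transcription factor DDIT3 from 5.43 ± 0.779 to 10.2 ± 2.23 CPM. CHAC1 and ATF3 missed the FPKM minimum of the tests and were tested in a fit with another filter. CHAC1 stood at 1.54 ± 1.14 and 2.38 ± 0.522 CPM (adjusted p = 0.414) and ATF3 at 3.83 ± 1.19 and 5.25 ± 0.603 CPM (adjusted p = 0.231).

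NRF2 targets, the antioxidant and detoxification genes of that transcription factor, rose in 25 of 27 members with 0 falls, and in 26 adjusted over the list alone (camera adjusted p = 8.63e-70, adjusted p = 0.000228 with an estimated correlation). Beside AKR1C2, AKR1C3 and SLC7A11 these included the ferritin light chain FTL, from 276 ± 9.25 to 618 ± 43.1 CPM. Iron handling genes split, with 7 of 19 higher, 3 lower and 9 not passing, and with 7 rises and 4 falls adjusted over the list alone. Their median was -0.01 and their mean 0.18 on the log2 scale, and camera gave a rise (adjusted p = 0.0028, adjusted p = 0.0932 with an estimated correlation). FTL, HMOX1 and FTH1 led the risers. Lysosome and autophagy genes rose in 12 of 19 members with 0 falls, and in 13 adjusted over the list alone (camera adjusted p = 1.49e-15, adjusted p = 0.0069 with an estimated correlation). The autophagy receptor SQSTM1, itself an NRF2 target, went from 478 ± 5.46 to 859 ± 32 CPM, WIPI1 rose 1.96-fold and the protease CTSD 1.78-fold. All 3 tested metallothioneins rose, also adjusted over the list alone, by 0.29 for MT1E and 0.54 for MT2A on the log2 scale, with a median of 0.51.

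Genes of inflammation and early signalling moved upward. In the list of NF-kB targets and inflammatory cytokines 12 of 15 rose and 0 fell, and 13 rose adjusted over the list alone (camera adjusted p = 3.51e-28, adjusted p = 0.00497 with an estimated correlation). Among them was the chemokine CXCL2, which rose from 2.59 ± 0.212 to 12.9 ± 2.5 CPM. Immediate early genes had 10 rises, 0 falls and 6 not passing of 16, and 13 rises and 1 fall adjusted over the list alone (camera adjusted p = 1.73e-21, adjusted p = 0.00973 with an estimated correlation). The MAP kinase phosphatases DUSP5 and DUSP6 rose 2.8-fold and 2.18-fold, and IER3 rose from 62.8 ± 3.17 to 150 ± 11 CPM. Mesenchymal and TGF-beta genes rose in 4 of 16 members and fell in 1, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0357, adjusted p = 0.36 with an estimated correlation). TGFB1 rose 1.52-fold and the transcription factor SNAI2 1.5-fold. Of 22 p53 targets 4 rose, 2 fell and 16 did not pass, and adjusted over the list alone 6 rose and 2 fell (camera adjusted p = 0.0415, adjusted p = 0.18 with an estimated correlation). The share of p53 targets called is near the 24.9% of all protein-coding loci. The risers GDF15 and SAT1 also stand in other lists, and the call of GADD45A, 1.65-fold higher, ended without RSL3 replicate 1 (adjusted p = 0.0704).

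Hypoxia and glycolysis genes rose in 17 of 20 members with 0 falls, and in 18 with 1 fall adjusted over the list alone (camera adjusted p = 9.42e-13, adjusted p = 0.107 with an estimated correlation). NDRG1, a gene induced by low oxygen and by iron chelation, went from 38.2 ± 4.94 to 131 ± 32.4 CPM (adjusted p = 0.00145), and the glycolytic regulator PFKFB4 rose 1.65-fold. Targets of ATF4 and the amino acid response rose in 13 of 26 and fell in 1, and 15 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.05e-10, adjusted p = 0.022 with an estimated correlation). GDF15, SLC7A11 and DDIT3 rose most. Endoplasmic reticulum chaperones had 8 rises, 0 falls and 10 not passing of 18, and 8 rises adjusted over the list alone (camera adjusted p = 2.22e-08, adjusted p = 0.0764 with an estimated correlation). The disulphide isomerases PDIA4 and PDIA3 rose 1.62-fold and 1.32-fold, and HSP90B1 rose 1.47-fold. Heat shock genes went the other way in 8 of 16, with 2 rises, and with 3 rises and 8 falls adjusted over the list alone (camera adjusted p = 0.0151, adjusted p = 0.341 with an estimated correlation). HSPA4L, the mitochondrial chaperonin HSPD1 and CHORDC1 fell 1.23-fold, 1.22-fold and 1.18-fold.

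Cholesterol synthesis genes rose in 15 of 23 members with 0 falls, and in 19 adjusted over the list alone (camera adjusted p = 5.28e-11, adjusted p = 0.00497 with an estimated correlation). The sterol enzymes MSMO1 and HSD17B7 each rose 1.54-fold. Mitosis genes fell in 16 of 20 with 0 rises, likewise adjusted over the list alone (camera adjusted p = 5.67e-08, adjusted p = 0.00497 with an estimated correlation). The kinesin KIF20A fell from 131 ± 5.85 to 98.8 ± 2.69 CPM, cyclin CCNA2 1.24-fold and CENPF 1.23-fold. Replication-dependent histones rose in 8 of 15 with 0 falls, and in 9 adjusted over the list alone (camera adjusted p = 7.57e-05, adjusted p = 0.18 with an estimated correlation). H2AC8, H1-2 and H1-4 rose 1.3-fold, 1.28-fold and 1.19-fold. Nuclear genes of oxidative phosphorylation fell in 5 of 23 with 0 rises, and in 5 adjusted over the list alone (camera adjusted p = 0.0196, adjusted p = 0.18 with an estimated correlation). ATP5F1B and UQCRFS1 fell 1.17-fold and 1.15-fold, and NDUFS3 1.14-fold, a call that ended without DMSO replicates 1 or 2 or RSL3 replicates 2 or 3 (adjusted p up to 0.209). Ribosomal protein genes fell in 2 of 24, in 1 adjusted over the list alone, and rose in 0 (camera adjusted p = 0.0163, adjusted p = 0.394 with an estimated correlation). RPS2 fell 1.08-fold, a call that ended without DMSO replicate 1 or RSL3 replicate 3 (adjusted p up to 0.0875).

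The camera test did not move 6 lists. DNA replication genes had 2 rises and 3 falls of 20, also adjusted over the list alone (adjusted p = 0.328), and interferon response genes 0 and 3 of 14, also adjusted over the list alone (adjusted p = 0.112). Fatty acid synthesis genes had 4 rises and 2 falls of 15, and 5 and 2 adjusted over the list alone (adjusted p = 0.16), and selenoproteins 3 and 3 of 18, and 3 and 4 adjusted over the list alone (adjusted p = 0.591). Epithelial and alveolar genes had 0 rises and 2 falls of 5, also adjusted over the list alone (adjusted p = 0.535, median -0.05, mean 0.01, test downward). The list of named long noncoding RNAs had 7 rises and 7 falls of 27, also adjusted over the list alone (adjusted p = 0.376), with a median of -0.09, a mean of 0.12 on the log2 scale and a test upward. Markers of other cell types were scarce, with 3 fibroblast, 3 blood and 1 endothelial marker expressed enough to test. No fibroblast or blood marker passed, while adjusted over the list alone 1 fibroblast marker was lower, and the endothelial marker EGFL7 rose by 0.91 on the log2 scale.

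Long noncoding RNAs were called in 116 of 1367 tested loci, 63 higher and 53 lower. LUCAT1, a transcript induced by oxidative stress, rose from 44.6 ± 2.38 to 156 ± 9.16 CPM (3.49-fold, SE 0.0554 on the log2 scale, adjusted p = 1.79e-18). LINC01629 rose from 0.288 ± 0.0244 to 3.27 ± 0.476 CPM (adjusted p = 7.09e-08), a call that DESeq2 did not make, and the locus AC010343;AC034223 rose 3.26-fold. PCDH9-AS4 fell from 28 ± 3.23 to 14.9 ± 0.947 CPM (adjusted p = 1.38e-07). AC026124 (locus MSTRG.9279, not the locus of that name with most counts) and PSPC1-AS2 fell with adjusted p of 0.0337 and 0.0375. The AC026124 call ended without any 1 DMSO library or without RSL3 replicates 1 or 2 (adjusted p up to 0.108), and the PSPC1-AS2 call without DMSO replicates 2 or 3 or RSL3 replicates 1 or 2 (adjusted p up to 0.162).

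Across the 17297 tested loci RSL3 changed 2854, with 1564 higher and 1290 lower, and 111 of the rises and 28 of the falls were at least 2-fold. Protein-coding loci were called in 24.9% (2388 of 9588), 1314 higher and 1074 lower. With both directions together, the shares called of ferroptosis drivers, p53 targets, mesenchymal genes and oxidative phosphorylation genes lay near that value. The libraries of both groups did not overlap in 30.8% of the loci, against the 10% that chance gives. Camera moved 15 lists up and 4 down, and 9 of these 19 calls held with an estimated correlation.

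RSL3 plus Fer-1 against RSL3 asks what changes when Fer-1 is added to RSL3. Lipid peroxidation was not measured here. Of the 690 falls and 427 rises, 140 and 153 were in loci not called in RSL3 against DMSO. CCN1 and DDIT4 are examples, at 0.07 and 0.22 on the log2 scale with RSL3 (edgeR adjusted p = 0.345 and 0.116). With Fer-1 added they lay below DMSO, at -0.41 and -0.32. CXCL8 fell from 51.8 ± 9.32 to 14.3 ± 0.735 CPM, or 3.63-fold, and GDF15 from 13.6 ± 2.41 to 3.79 ± 0.216 CPM, or 3.58-fold (SD, n = 3). NDRG1 went from 131 ± 32.4 to 49.5 ± 1.76 CPM, IER3 from 150 ± 11 to 68.1 ± 3.78 CPM, and the vasodilator peptide gene ADM from 16.6 ± 1.94 to 8.25 ± 0.641 CPM. In the other direction OLR1 rose from 14 ± 2.25 to 25.3 ± 1.93 CPM. The pyruvate dehydrogenase kinase PDK4 rose from 32.4 ± 1.11 to 53.7 ± 3.92 CPM, and CPS1-IT1, which lies within the CPS1 locus, the phosphodiesterase PDE1A and the tetraspanin TSPAN8 rose 1.8-fold, 1.55-fold and 1.54-fold.

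The edgeR log2 changes were -1.86 for CXCL8 (SE 0.139, adjusted p = 2.94e-07), -1.84 for GDF15 (SE 0.222, adjusted p = 1.17e-05), -1.14 for IER3 (SE 0.0583, adjusted p = 4.89e-13) and 0.85 for OLR1 (SE 0.106, adjusted p = 3.01e-06). NDRG1 had an adjusted p of 0.00928 that rose to 0.0503 without RSL3 plus Fer-1 replicate 2. GPX4 differed by -0.12 on the log2 scale (adjusted p = 0.74) and PTGS2, at 15.1 ± 2.01 CPM, by -0.11 (adjusted p = 0.74), and without RSL3 replicate 1 these differences were 0.03 and 0.02. TFRC, ACSL4 and AIFM2 differed by 0.05, -0.06 and -0.26 (adjusted p = 0.454, 0.483 and 0.103), and CHAC1 and ATF3 by -1.16 and -0.60 (adjusted p = 0.153 and 0.169).

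NF-kB targets and inflammatory cytokines fell in 11 of 15 members with 0 rises, and in 12 adjusted over the list alone (camera adjusted p = 1.17e-26, adjusted p = 0.0124 with an estimated correlation). IL1A fell 3.13-fold and CXCL2 2.34-fold. Hypoxia and glycolysis genes fell in 13 of 20 with 0 rises, and adjusted over the list alone 1 rose and 16 fell (camera adjusted p = 2.16e-18, adjusted p = 0.0686 with an estimated correlation). The mitophagy receptor BNIP3 fell from 57.6 ± 8.12 to 36.5 ± 0.332 CPM. Immediate early genes had 9 falls, 1 rise and 6 not passing of 16, and the same numbers adjusted over the list alone (camera adjusted p = 8.07e-14, adjusted p = 0.0503 with an estimated correlation). DUSP5 fell 2.02-fold and the AP-1 subunit JUN 1.88-fold. Mesenchymal and TGF-beta genes fell in 6 of 16 with 0 rises, and adjusted over the list alone 1 rose and 7 fell (camera adjusted p = 7.31e-05, adjusted p = 0.115 with an estimated correlation). The matricellular gene CCN1 fell 1.39-fold and SNAI2 1.33-fold, and the latter call ended without RSL3 replicate 2 or RSL3 plus Fer-1 replicates 1 or 2 (adjusted p up to 0.0841).

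NRF2 targets fell in 6 of 27 members with 0 rises, and in 7 adjusted over the list alone (camera adjusted p = 0.000132, adjusted p = 0.0686 with an estimated correlation). HMOX1 fell from 23.1 ± 3.25 to 15.4 ± 0.634 CPM, a call that ended without RSL3 replicate 1 (adjusted p = 0.06), FTH1 fell from 1040 ± 82.3 to 739 ± 44.3 CPM, and TXNRD1 fell 1.14-fold. FTL fell 1.31-fold (adjusted p = 0.0234), and that call ended in 6 of the 9 leave-outs, DMSO replicates 2 and 3, RSL3 replicates 1 and 2, and RSL3 plus Fer-1 replicates 1 and 2, with adjusted p up to 0.0944. Suppressors of ferroptosis fell in 4 of 18 and rose in 1, and adjusted over the list alone 2 rose and 5 fell (camera adjusted p = 0.0246, adjusted p = 0.0933 with an estimated correlation). SLC7A11 fell 1.17-fold (adjusted p = 0.000337) and the acyltransferase MBOAT2 1.24-fold. Response markers fell in 4 of 9 with 0 rises, also adjusted over the list alone (camera adjusted p = 7.78e-05, adjusted p = 0.0686 with an estimated correlation). Of these, DDIT4 fell 1.45-fold and DDIT3 1.63-fold, and the DDIT3 call ended without RSL3 replicate 1 or RSL3 plus Fer-1 replicates 2 or 3 (adjusted p up to 0.141). The metallothioneins fell in 3 of 3 members, also adjusted over the list alone, with -0.36 for MT1E, -0.49 for MT2A and a median of -0.49 on the log2 scale.

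ATF4 targets fell in 6 of 26 and rose in 2, and adjusted over the list alone 4 rose and 8 fell (camera adjusted p = 8.23e-05, adjusted p = 0.104 with an estimated correlation). The phosphatase regulator PPP1R15A fell 2.12-fold and the glycoprotein hormone STC2 fell from 149 ± 6.75 to 75.4 ± 3 CPM. Endoplasmic reticulum chaperones fell in 6 of 18 with 0 rises, and in 7 adjusted over the list alone (camera adjusted p = 0.00388, adjusted p = 0.264 with an estimated correlation). HERPUD1 fell 1.23-fold and HSPA5 1.17-fold. HSP90B1 fell 1.14-fold, a call that ended without RSL3 replicates 1 or 2 or RSL3 plus Fer-1 replicates 1 or 2 (adjusted p up to 0.0882). Of 22 p53 targets 4 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 0.00156, adjusted p = 0.0686 with an estimated correlation). Besides GDF15, GADD45A fell 1.89-fold and SAT1 1.57-fold. Lysosome genes fell in 6 of 19 with 0 rises, and in 9 adjusted over the list alone (camera adjusted p = 6.74e-07, adjusted p = 0.0647 with an estimated correlation). CTSL fell 1.29-fold and CTSD 1.21-fold. NEU1 fell 1.25-fold, a call that ended without any 1 RSL3 library or without RSL3 plus Fer-1 replicate 1 (adjusted p up to 0.177). Cholesterol synthesis genes fell in 2 of 23 with 0 rises, and in 5 adjusted over the list alone (camera adjusted p = 0.000105, adjusted p = 0.0503 with an estimated correlation). INSIG1 fell 1.28-fold, a call that ended without RSL3 replicates 1 or 3 or RSL3 plus Fer-1 replicates 1 or 2 (adjusted p up to 0.147).

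Mitosis genes rose in 11 of 20 members with 0 falls, and in 13 adjusted over the list alone (camera adjusted p = 4.47e-09, adjusted p = 0.0124 with an estimated correlation). The survivin gene BIRC5 rose from 93.1 ± 4.07 to 114 ± 2.65 CPM, KIF20A 1.2-fold and CENPF 1.19-fold. Heat shock genes rose in 4 of 16 with 0 falls, and in 7 adjusted over the list alone (camera adjusted p = 0.00192, adjusted p = 0.262 with an estimated correlation). The co-chaperones FKBP4 and DNAJA1 rose 1.14-fold and 1.13-fold. HSPA4L rose 1.11-fold, a call that ended without RSL3 replicates 1 or 2 or RSL3 plus Fer-1 replicate 2 (adjusted p up to 0.064). For DNA replication genes camera with the preset correlation gave a rise, with 0 of 20 members called, also adjusted over the list alone (camera adjusted p = 0.0408, adjusted p = 0.115 with an estimated correlation). MCM3 had the smallest p, with 0.12 on the log2 scale (adjusted p = 0.0613). The other tested lists did not pass. Drivers of ferroptosis had 0 rises and 1 fall of 12 (adjusted p = 0.283), interferon genes 1 and 0 of 14 (adjusted p = 0.111), iron handling 0 and 5 of 19 (adjusted p = 0.111, median 0.02, mean -0.07), selenoproteins 1 and 1 of 18 (adjusted p = 0.687, median 0.02, mean -0.01, test upward) and oxidative phosphorylation 2 and 0 of 23 (adjusted p = 0.111). Ribosomal proteins had 0 called of 24 (adjusted p = 0.737) and histones 0 of 15 (adjusted p = 0.837), and in these 7 lists the counts adjusted over the list alone were equal. Fatty acid genes had 4 rises and 2 falls of 15, and 5 and 2 adjusted over the list alone (adjusted p = 0.269), and epithelial genes 0 called of 5, and 2 falls adjusted over the list alone (adjusted p = 0.14). Among markers of other cell types LYZ fell by 1.19 on the log2 scale (adjusted p = 0.00446), and the other 2 blood markers, the 3 fibroblast markers and the 1 endothelial marker did not pass. Adjusted over the list alone, 2 blood markers and the endothelial marker were lower.

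Long noncoding RNAs were called in 63 of 1367 loci, 24 higher and 39 lower, and the count was 39 without RSL3 replicate 1. LUCAT1 fell from 156 ± 9.16 to 87.3 ± 2.6 CPM (adjusted p = 3.46e-11), UCA1 from 15.6 ± 1.38 to 7.39 ± 1.34 CPM (adjusted p = 9.2e-06), and the LINC-PINT locus 1.56-fold. LINC01629 and LINC01537 fell 3.18-fold and 2.5-fold, while SH3BP5-AS1 rose from 13.9 ± 1.4 to 24 ± 5.24 CPM. AL450306 rose with an adjusted p of 0.0362, a call that ended without RSL3 replicate 1 or any 1 RSL3 plus Fer-1 library (adjusted p up to 0.237). AC008966 (locus MSTRG.28289, not the locus of that name with most counts) fell with an adjusted p of 0.0267. That call ended without RSL3 replicates 1 or 3 or RSL3 plus Fer-1 replicates 2 or 3 (adjusted p up to 0.15). In the list of named long noncoding RNAs 3 of 27 rose and 7 fell, also adjusted over the list alone, with a median of 0.01, a mean of -0.08 on the log2 scale and a camera call downward (adjusted p = 0.0485, adjusted p = 0.108 with an estimated correlation).

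With Fer-1 added, 1117 of the 17297 loci differed from RSL3 alone, 427 higher and 690 lower, and 12 and 32 of these by at least 2-fold. Protein-coding loci were called in 9.42% (903 of 9588). The groups did not overlap in 22.7% of the loci against 10% by chance. Limma on log2(FPKM + 1) called 563 loci and 35 long noncoding RNAs, and 2 of the 16 list calls, 3 up and 13 down, held with an estimated correlation.

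RSL3 plus Fer-1 against DMSO asks what remains different from vehicle once Fer-1 is present. AKR1C2 stood at 45.1 ± 6.3 against 6.82 ± 0.632 CPM, 6.6-fold higher, and AKR1C3 at 95.6 ± 4.13 against 21.8 ± 3 CPM, 4.37-fold higher (SD, n = 3). CXCL8 was 3.99-fold and IL11 3.19-fold above DMSO, at 14.3 ± 0.735 and 28.7 ± 3.5 CPM. SLC7A11 was 2.02-fold higher, at 885 ± 33.5 CPM, and PDK4 2.28-fold higher. The mono-ADP-ribosyltransferase gene TIPARP, a target of the aryl hydrocarbon receptor, was lower at 57.7 ± 3.04 against 115 ± 8.41 CPM, IGFBP3 1.97-fold lower and the guanine deaminase GDA 1.66-fold lower.

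Their edgeR log2 changes were 2.72 for AKR1C2 (SE 0.104, adjusted p = 4.26e-15), 2.13 for AKR1C3 (SE 0.0736, adjusted p = 4.07e-15), 1.67 for IL11 (SE 0.0946, adjusted p = 1.17e-12), 1.01 for SLC7A11 (SE 0.0388, adjusted p = 6.86e-14) and -0.99 for TIPARP (SE 0.0571, adjusted p = 1.53e-12). SEL1L3 was 2.02-fold higher and the axon guidance gene NTN4 1.49-fold lower. The matricellular gene THBS1 was 1.65-fold lower (adjusted p = 0.0126), a call that ended without RSL3 plus Fer-1 replicates 2 or 3 (adjusted p up to 0.0632). WFDC21P was 1.68-fold lower (adjusted p = 0.0442), and that call ended in 8 of the 9 leave-outs, the exception being RSL3 plus Fer-1 replicate 1, with adjusted p up to 0.199.

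NRF2 targets were higher in 24 of 27 members with 0 lower, and in 26 adjusted over the list alone (camera adjusted p = 1.63e-96, adjusted p = 9e-05 with an estimated correlation). Suppressors of ferroptosis had 7 higher, 1 lower and 10 not passing of 18, and 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.32e-08, adjusted p = 0.00828 with an estimated correlation). The glutathione synthesis gene GCLM was 1.44-fold and FTH1 1.33-fold above DMSO. Response markers were higher in 4 of 9 and lower in 1, and in 5 and 1 adjusted over the list alone (camera adjusted p = 9.08e-08, adjusted p = 0.0411 with an estimated correlation). PTGS2 was 2.07-fold (adjusted p = 5.17e-06) and the pseudokinase TRIB3 1.37-fold higher. HMOX1, GPX4, ACSL4, AIFM2 and DDIT3 differed from DMSO by 0.36, -0.09, 0.05, 0.04 and 0.21 on the log2 scale (adjusted p = 0.134, 0.821, 0.63, 0.885 and 0.62), and AIFM2 was -0.07 without RSL3 plus Fer-1 replicate 2. TXNRD1 was 1.32-fold higher. TFRC was 1.08-fold higher (adjusted p = 0.0182), a call that ended without DMSO replicate 3 or RSL3 plus Fer-1 replicates 2 or 3 (adjusted p up to 0.111). CHAC1 and ATF3 differed by -0.53 and -0.14 (adjusted p = 0.667 and 0.873). Iron handling genes were higher in 4 of 19 with 0 lower, and 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0027, adjusted p = 0.101 with an estimated correlation). FTL was 1.72-fold higher and PCBP1 1.09-fold, and the PCBP1 call ended without any 1 of the DMSO or RSL3 plus Fer-1 libraries (adjusted p up to 0.175).

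Lysosome genes were higher in 6 of 19 with 0 lower, and in 7 adjusted over the list alone (camera adjusted p = 7.94e-10, adjusted p = 0.0303 with an estimated correlation). SQSTM1 was 1.53-fold, CTSD 1.47-fold and the galactosidase GLA 1.42-fold above DMSO. Immediate early genes were higher in 7 of 16 with 0 lower, and 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.37e-09, adjusted p = 0.059 with an estimated correlation). The nuclear receptor NR4A1 was 1.62-fold and DUSP1 1.46-fold higher, and KLF4 1.51-fold, a call that ended without RSL3 plus Fer-1 replicates 1 or 2 (adjusted p up to 0.0707). NF-kB targets had 5 higher, 1 lower and 9 not passing of 15, and 8 higher and 2 lower adjusted over the list alone (camera adjusted p = 1.88e-09, adjusted p = 0.0495 with an estimated correlation). CXCL2 was 2.14-fold higher. Cholesterol synthesis genes were higher in 5 of 23 with 0 lower, and in 7 adjusted over the list alone (camera adjusted p = 7.7e-07, adjusted p = 0.0255 with an estimated correlation). FDFT1 was 1.26-fold higher, and MSMO1 1.27-fold, a call that ended without DMSO replicates 1 or 2 or any 1 RSL3 plus Fer-1 library (adjusted p up to 0.195). Fatty acid genes were higher in 5 of 15 and lower in 1, also adjusted over the list alone (camera adjusted p = 0.00241, adjusted p = 0.0894 with an estimated correlation). Malic enzyme ME1 was 1.38-fold, FADS1 1.29-fold and the desaturase SCD 1.21-fold higher.

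ATF4 targets were higher in 9 of 26 and lower in 3, and 11 higher and 4 lower adjusted over the list alone (camera adjusted p = 5.67e-06, adjusted p = 0.0883 with an estimated correlation). Asparagine synthetase ASNS was 1.39-fold higher. The glycine transporter SLC6A9 was 1.47-fold higher, a call that ended without DMSO replicate 1 or RSL3 plus Fer-1 replicate 3 (adjusted p up to 0.063). Endoplasmic reticulum chaperones were higher in 7 of 18 with 0 lower, and 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.6e-06, adjusted p = 0.119 with an estimated correlation). PDIA4 was 1.44-fold, HSP90B1 1.29-fold and HYOU1 1.25-fold higher. Histones were higher in 6 of 15 with 0 lower, and in 9 adjusted over the list alone (camera adjusted p = 7.7e-07, adjusted p = 0.125 with an estimated correlation). H2AC8 was 1.3-fold, H1-4 1.24-fold and H2BC12 1.2-fold higher. For ribosomal protein genes only camera with the preset correlation gave a fall, with 0 of 24 members called, also adjusted over the list alone (camera adjusted p = 0.00434, adjusted p = 0.402 with an estimated correlation). RPL7 had the smallest p, with -0.14 on the log2 scale (adjusted p = 0.0538). Epithelial genes were lower in 3 of 5 with 0 higher, also adjusted over the list alone (camera adjusted p = 0.0262, adjusted p = 0.255 with an estimated correlation). These were the keratins KRT8, 1.13-fold, KRT18, 1.11-fold, and KRT7, 1.09-fold, a call that ended without DMSO replicates 1 or 3 or RSL3 plus Fer-1 replicate 1 (adjusted p up to 0.128).

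Hypoxia and glycolysis genes did not pass here, with 3 higher and 3 lower of 20, and 5 and 3 adjusted over the list alone (adjusted p = 0.59), nor did mitosis genes, with 0 higher and 1 lower of 20, and 0 and 2 adjusted over the list alone (adjusted p = 0.267). Targets of p53 had 1 higher and 2 lower of 22, and 2 and 3 adjusted over the list alone (adjusted p = 0.825, median -0.02, mean 0.02), and heat shock genes 2 and 2 of 16, and 3 and 3 adjusted over the list alone (adjusted p = 0.825, median -0.02, mean 0.01), both with a test downward. Selenoproteins had 3 higher and 2 lower of 18, and 3 and 3 adjusted over the list alone (adjusted p = 0.231). For the remaining lists the counts adjusted over the list alone were equal. These were mesenchymal genes with 0 higher and 2 lower of 16 (adjusted p = 0.22), drivers of ferroptosis with 3 and 0 of 12 (adjusted p = 0.0559), DNA replication with 2 and 0 of 20 (adjusted p = 0.513), interferon genes with 1 and 2 of 14 (adjusted p = 0.683), oxidative phosphorylation with 0 and 1 of 23 (adjusted p = 0.181), and named long noncoding RNAs with 4 and 4 of 27 (adjusted p = 0.911, median -0.01, mean 0.04, test downward). None of the 3 metallothioneins, 3 blood markers or 1 endothelial marker passed. Of 3 fibroblast markers the locus that holds PDGFRA was lower, with -0.26 on the log2 scale, and all 3 were lower adjusted over the list alone.

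Long noncoding RNAs were called in 56 of 1367 loci, 33 higher and 23 lower. LUCAT1 was 1.96-fold above DMSO (adjusted p = 1.17e-12), SLC7A11-AS1, transcribed opposite to SLC7A11, stood at 19.6 ± 1.74 against 10 ± 2.25 CPM (adjusted p = 1.08e-05), and AL391056 was 2.55-fold higher (adjusted p = 0.000183). The SLC7A11-AS1 locus overlaps that of SLC7A11, and their log2 changes were 0.97 and 1.01. The labels do not say whether the libraries were stranded, so reads of SLC7A11 may be part of the antisense value. AC019080 (locus MSTRG.21235), AC138028 (locus MSTRG.15008) and Z83745 were lower with adjusted p of 0.0307, 0.0312 and 0.0426. The loci given for AC019080 and AC138028 are not those of that name with most counts. The AC019080 call ended without any 1 DMSO library or RSL3 plus Fer-1 replicates 2 or 3 (adjusted p up to 0.168). The AC138028 call, where the libraries of the groups overlapped, ended without DMSO replicates 1 or 2 or RSL3 plus Fer-1 replicates 1 or 2 (adjusted p up to 0.199). The Z83745 call ended without any 1 DMSO library or RSL3 plus Fer-1 replicates 1 or 3 (adjusted p up to 0.234).

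In all 1157 loci differed from DMSO with Fer-1 present, 697 higher and 460 lower, and 28 and 10 of these by at least 2-fold, and the groups did not overlap in 23.3% of the loci against 10% by chance. Protein-coding loci were called in 10.3% (991 of 9588). The count was 760 without RSL3 plus Fer-1 replicate 2 and 711 without replicate 3, and limma on log2(FPKM + 1) called 505 loci and 19 long noncoding RNAs. Of the 14 list calls, 12 up and 2 down, 6 held with an estimated correlation.

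**Figure D2:**
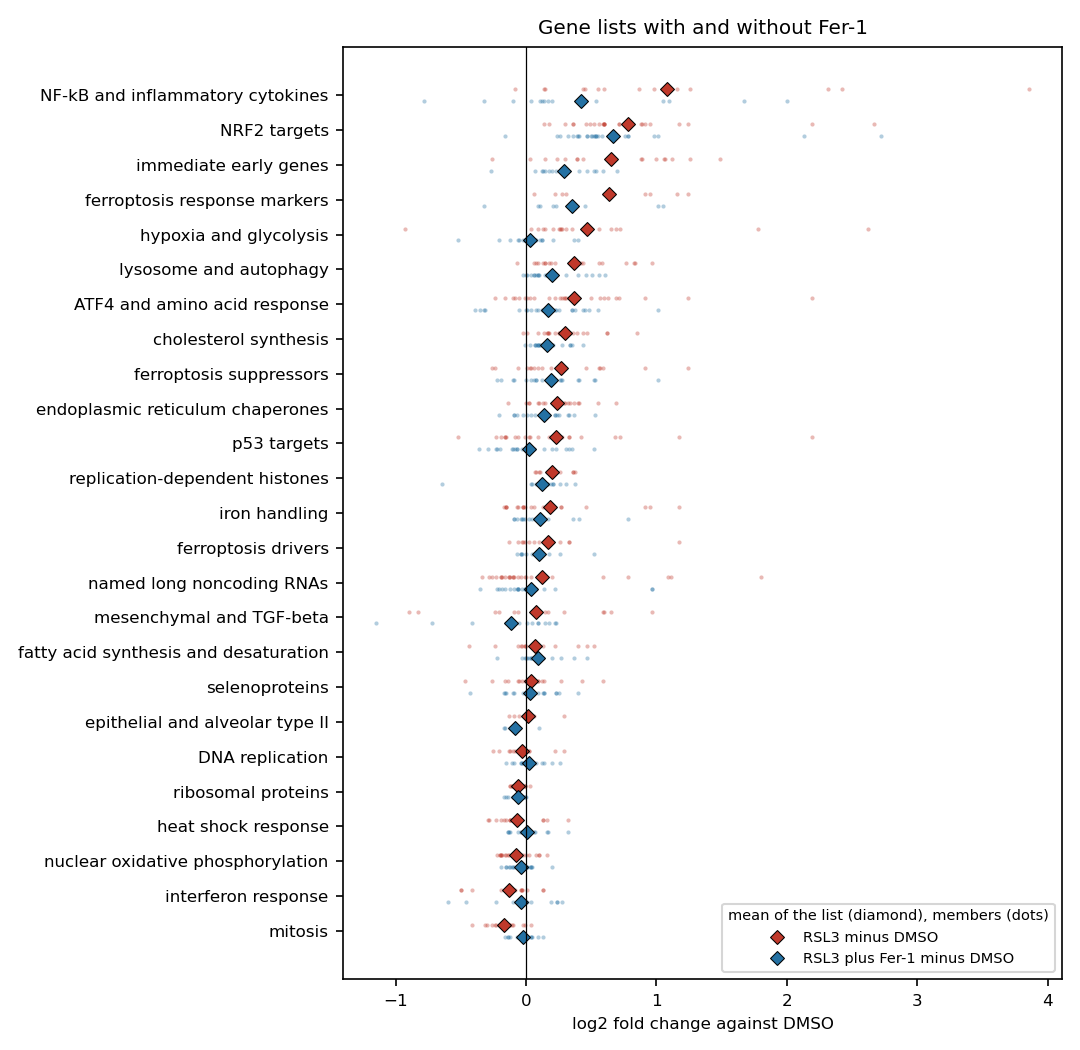
Log2 fold change against DMSO (horizontal axis) of 25 gene lists, with diamonds for the list mean and dots for its tested members, for RSL3 (red) and RSL3 plus Fer-1 (blue). NRF2 targets averaged 0.78 and 0.67, with 25 and 24 of 27 members higher, while hypoxia genes averaged 0.47 and 0.03.

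Setting the comparisons side by side asks which RSL3 changes were opposed when Fer-1 was added. A locus is called reversed when both comparisons call it in opposite directions. No library had Fer-1 without RSL3, so a reversal may also be an effect of Fer-1 itself. Of the 1564 loci that rose with RSL3, 544 (34.8%) were lower with Fer-1 than with RSL3 alone, among them CXCL8, GDF15, IER3 and LUCAT1. Of the 1290 that fell, 266 (20.6%) were higher with Fer-1, among them OLR1 and KIF20A. Together 810 of 2854 loci (28.4%) were reversed, and 854 (29.9%) were still called in the RSL3 direction against DMSO, among them AKR1C2, AKR1C3, IL11, SLC7A11 and SQSTM1. The sets overlap, in 151 risers and 30 fallers, and CXCL8, LUCAT1, IL11, SLC7A11 and SQSTM1 are in both. Reversed loci no longer called against DMSO numbered 377 risers and 226 fallers, and 8 and 6 loci moved further in the RSL3 direction with Fer-1. Called against DMSO in the direction opposite to RSL3 were 16 risers and 10 fallers. Of the falls with Fer-1 78.8% and of the rises 62.3% were reversals of an RSL3 change, and 140 falls and 153 rises were in loci not called in RSL3 against DMSO.

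Independent lists would give 62.4 and 31.8 reversed loci, and simulated unchanged groups that share the RSL3 libraries gave 0.15 on average and at most 1. The simulated groups averaged only 1.2 calls in RSL3 against DMSO and 1.15 in RSL3 plus Fer-1 against RSL3. A small overlap was thus set in advance, and shared noise in changed loci was not simulated. Limma on log2(FPKM + 1) gave 427 reversed loci. Independent lists would give 63 and 34.3 loci still called against DMSO, where 537 and 317 were found. Part of both overlaps may come from the shared libraries, since 3 libraries of a group are too few to split into separate sets of at least 2. The part of the RSL3 change that remained with Fer-1, estimated across the 17297 loci with a correction for the shared DMSO noise, was 0.46 (jackknife SE 0.0815), from 0.42 to 0.49 on leaving out 1 library. The covariance of the changes that share DMSO was 0.0735, against 0.0457 in the simulated unchanged groups.

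**Figure D3:**
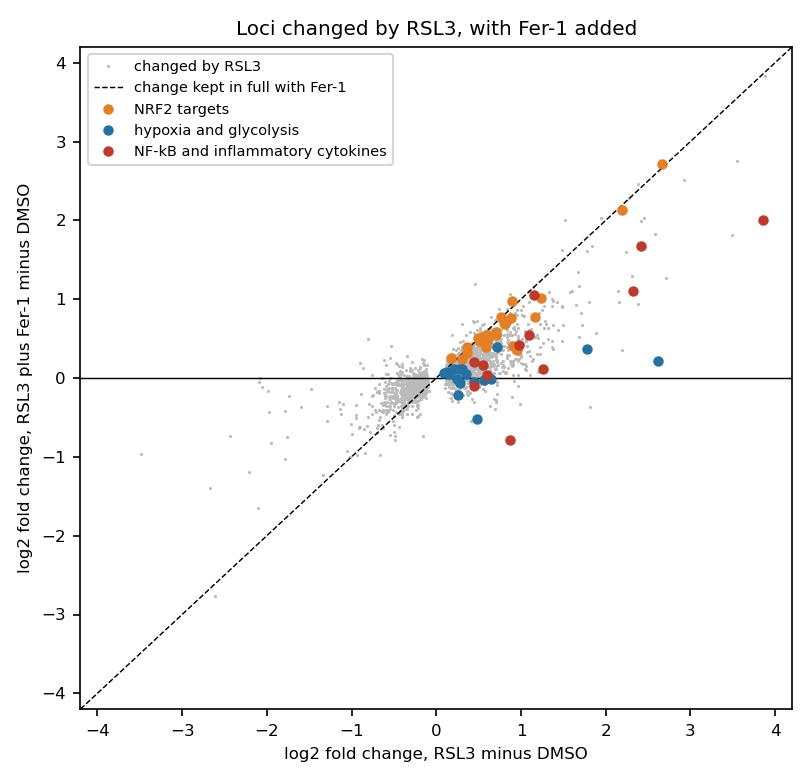
Log2 fold change of RSL3 plus Fer-1 minus DMSO (vertical axis) against that of RSL3 minus DMSO (horizontal axis) for the loci called in RSL3 against DMSO, with NRF2 targets in orange, hypoxia and glycolysis genes in blue and NF-kB targets in red. Points on the dashed line kept the RSL3 change in full, as AKR1C2 did with 2.67 and 2.72, while NDRG1 rose by 1.78 with RSL3 and stood at 0.37 with Fer-1, and 2 of the 2854 loci lie outside the axes.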

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

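No test of this part was chosen after its result was seen. The loci without a gene name, which were left out of the comparisons of the report, were tested in a fit of the same model together with the named loci, since a signal in data that the report does not use calls for a closer look. Of 708 such loci expressed enough to test, edgeR called 45 in RSL3 against DMSO, 21 higher and 24 lower. It called 16 in RSL3 plus Fer-1 against RSL3, 8 higher and 8 lower, and 16 in RSL3 plus Fer-1 against DMSO, again 8 higher and 8 lower. At an unadjusted p under 0.05 the numbers were 104, 78 and 67. No explanation was tested for these loci, which the table gives an identifier and a position but no name.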

How the results depend on the processing

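The filterByExpr filter, RLE factors and the restriction to loci of a single annotated gene were chosen only after the data were seen. Limma on log2(FPKM + 1) was the main test planned for a table of FPKM alone. The use of edgeR as the main test and of limma as an alternative was decided after the table was seen. Of 263 values of counts and of the remaining share under the alternatives, 215 stayed within 1.5 times the reported count or within 1 SE of the share, and 48 moved. Counts of genes in this section are counts of loci. RSL3 against DMSO called 2854 genes, and DESeq2 called 3262, RLE factors 2856 and the limma settings 1933 to 2101. With the replicate number as a block the counts were 2803, 1068 and 1141 for RSL3 against DMSO, RSL3 plus Fer-1 against RSL3 and RSL3 plus Fer-1 against DMSO, with 781 reversed genes. The numbers do not appear to pair the libraries, since correlations between like-numbered libraries ran from -0.29 to 0.16 and 2 of 9 libraries correlated best with their own number. For single named genes 3932 values kept direction and side of the threshold, 312 fell short of it, 15 newly passed and 6 reversed, with the cause not tested.

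Requiring at least a 2-fold change left 139, 44 and 38 loci, which follows from the stricter threshold. Many of these were not protein coding. With RSL3, 57 of 111 rises and 5 of 28 falls were. In RSL3 plus Fer-1 against RSL3, 1 of 12 rises and 15 of 32 falls were. Against DMSO, 12 of 28 rises and 3 of 10 falls were. Camera with an estimated correlation kept 9, 2 and 6 of 19, 16 and 14 lists, and fry gave 22, 19 and 15, with the cause not tested. An FPKM of at least 5, which left 4978 loci to test, gave 1796 genes for RSL3 against DMSO and 28, 16 and 15 long noncoding RNAs. The remaining share, 0.46, was 0.55 with no filter on low values and 0.56 with the filterByExpr filter, and the cause was not tested.

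Without trend and robust estimation 669 genes were called in RSL3 plus Fer-1 against RSL3, 621 in RSL3 plus Fer-1 against DMSO, and 487 were reversed. In RSL3 plus Fer-1 against RSL3, limma called 563 genes on log2(FPKM + 1), 535 with a pseudocount of 0.1, 602 with 5, 565 on TMM-rescaled FPKM, 559 after quantile normalisation and 565 with array weights. Long noncoding RNAs there numbered 35, 33, 37, 34, 34 and 33 in the same order. Against DMSO these settings called 505, 511, 499, 501, 502 and 569 genes and 19, 20, 19, 19, 19 and 21 long noncoding RNAs, and 427, 401, 457, 428, 421 and 420 genes were reversed. For all of these the cause was not tested.

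On leaving out 1 library, RSL3 plus Fer-1 against DMSO gave 711 to 1211 genes, lowest without RSL3 plus Fer-1 replicate 3, and RSL3 plus Fer-1 against RSL3 gave 39 to 66 long noncoding RNAs, lowest without RSL3 replicate 1. GPX4 in RSL3 against DMSO changed sign to -0.01 under quantile normalisation, and ran from -0.12 to 0.12 on leaving out 1 library, lowest without RSL3 replicate 1. In RSL3 plus Fer-1 against RSL3, GPX4 ran from -0.22 to 0.03 and PTGS2 from -0.20 to 0.02, both highest without RSL3 replicate 1. AIFM2 in RSL3 plus Fer-1 against DMSO ran from -0.07 to 0.15, lowest without RSL3 plus Fer-1 replicate 2. None of these passed the test under either setting. Gene lists were not run with DESeq2 or without trend, and the remaining share was not run with DESeq2, array weights, without trend or in fits of 6 libraries. A count of 0 allows up to 0.0658 to 0.077 CPM. CHAC1 and ATF3, at 1.54 and 3.83 CPM with DMSO, lie above that and missed only the FPKM minimum.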

Other observations

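The other splits of the libraries, the count of libraries with Fer-1 alone, the simulations for the loci of the second paragraph, the tally of ligand genes and the estimated correlation of the hypoxia list were tests chosen only after the result was seen, and so were the genes of the first 2 paragraphs and the KEGG pathways. The lists set against each other in the third paragraph were not fixed in advance either. ANGPTL4, an inhibitor of lipoprotein lipase, rose from 2.27 ± 0.63 to 14.8 ± 1.95 CPM (SD, n = 3), 6.53-fold (edgeR adjusted p = 4.34e-11), and fell to 5.48 ± 0.79 CPM with Fer-1 (adjusted p = 2.79e-06). Of 7 genes for ligands of the epidermal growth factor receptor, 4 were expressed enough to test, and all 4 rose with RSL3 and fell with Fer-1. EPGN rose 2.21-fold and fell 1.87-fold, EREG rose from 131 ± 6.13 to 210 ± 15 CPM and fell to 109 ± 3.85 CPM with Fer-1, TGFA rose 1.88-fold and fell 1.66-fold, and HBEGF rose 1.97-fold and fell 1.67-fold (adjusted p = 0.00239 and 0.0407). The receptor gene EGFR stood at 6480 ± 1650, 8850 ± 2380 and 7890 ± 10.3 CPM in DMSO, RSL3 and RSL3 plus Fer-1 and did not pass (adjusted p = 0.36 and 0.84). GPRC5A, an orphan receptor of lung epithelium in the locus GPRC5A;MIR614, rose from 517 ± 8.71 to 946 ± 30.4 CPM and fell to 601 ± 1.5 CPM. Of 269 KEGG pathways with 15 to 300 tested loci, camera passed 119 in RSL3 against DMSO, and 2 held with an estimated correlation, cytokine-cytokine receptor interaction with 26 rises and 2 falls of 65 and hematopoietic cell lineage with 14 and 2 of 27 (both adjusted p = 0.0384 with an estimated correlation). In RSL3 plus Fer-1 against RSL3 and against DMSO 71 and 47 pathways passed, and 0 held with an estimated correlation in either. The 2 pathways that held in RSL3 against DMSO share 6 called members. Rises among the members included CSF1, 1.9-fold, the oncostatin M receptor OSMR, 1.64-fold, and the integrin ITGA2, 1.96-fold.

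A separate set of 104 loci was not called in RSL3 against DMSO and was called in the same direction in both comparisons of RSL3 plus Fer-1, 52 higher and 52 lower. Both comparisons share the 3 RSL3 plus Fer-1 libraries, so agreement in direction is partly built in. In 20 simulations these loci and all uncalled loci were unchanged, and the other 3216 called loci kept their group means. They gave 36.1 such loci on average (27 to 47), 3.2 of them among the unchanged loci and 32.9 among the others. Chance in which calls pass may therefore account for part of the 104, and the simulations do not tell which loci. Among the lower loci TIPARP stood at 115 ± 8.41 CPM with DMSO, 114 ± 4.67 CPM with RSL3 and 57.7 ± 3.04 CPM with Fer-1 added. Its log2 change was -0.02 with RSL3 (adjusted p = 0.901) and -0.99 with RSL3 plus Fer-1 (adjusted p = 1.53e-12). Among the higher loci SIK1 and GLP2R stood 0.59 and 0.62 above DMSO on the log2 scale (adjusted p = 3.89e-08 and 3.08e-08). No theme of these loci was tested. With no library that had Fer-1 and no RSL3, an effect of Fer-1 itself and one that needs both compounds were not separated.

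NRF2 targets kept more of their RSL3 rise with Fer-1 than NF-kB, immediate early and hypoxia genes did, 85.4% of the mean log2 change in 27 members against 33.6% in 50, a difference of 51.8 percentage points (jackknife SE 4.19). NRF2 targets had the highest kept part of 15 lists and the pool holds the lowest, a choice of lists that was not planned. The SE makes no allowance for that choice. The lists pooled in the 33.6% differ, at 39.3% (SE 3.98) for NF-kB, 44.9% (SE 5.12) for immediate early and 7.12% (SE 8.51) for hypoxia genes. The hypoxia value ran from 2.57 to 12.3% on leaving out 1 library. The other 11 lists that passed in RSL3 against DMSO with a mean change of at least 0.15 on the log2 scale kept 11.4 to 70.2%. The lowest was that of p53 targets (SE 16.5), which ran from -3.39 to 19.9% on leaving out 1 library. Highest among them were ferroptosis suppressors at 70.2% (SE 6.42), histones at 66.9% (SE 26.5), iron handling at 60.8% (SE 8.3) and ferroptosis drivers at 58.3% (SE 8.5), with members shared with the NRF2 list not removed. Noise of the shared DMSO libraries would take the difference to near 0 when both changes use different DMSO libraries, and it stayed at 44.2 points or more in the 6 assignments. For hypoxia genes the list mean ranged only from -0.04 to 0.03 on the log2 scale between DMSO libraries. Exchanging these libraries could thus move the kept part of that list little, which limits what the test can show. Reads shared between near-identical genes or overlapping loci would do so without AKR1C2, AKR1C3, FTH1, FTL and joined loci, and the difference was 48.6 points (SE 5.42). AKR1C1 of the same list was not among the genes taken out, so that test covers only the loci named. An effect of Fer-1 that does not depend on RSL3 stays open, since 0 libraries had Fer-1 alone. No biological explanation was tested.

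Of 20 hypoxia and glycolysis genes 17 rose with RSL3 and 13 fell with Fer-1, and the list mean lay 0.62, 0.26 and 0.48 above the DMSO mean on the log2 scale in the 3 RSL3 libraries and at -0.01, 0.04 and 0.07 in those with Fer-1. RSL3 replicate 1 standing apart does not account for it, since 14 of 20 members still rose without that library and 11 fell with Fer-1. A spread between libraries that these genes share could not be ruled out, as the adjusted p with an estimated correlation was 0.107 for the rise and 0.0686 for the fall. Oxygen in the cultures and iron inside the cells were not measured, so no biological explanation was tested.

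At 0 counts in 1 library and above 100 in another of the same group were 33 loci, 29 of them without an annotated transcript type and 0 called in any comparison by edgeR. Reads assigned to an overlapping locus instead may explain a part, since in 36.7% of the 30 loci with an overlapping locus at least 50% of the missing counts appeared there. That share lies between the bounds set in advance, so the cause of these gaps stays open, and no biological explanation was tested.

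With 3 libraries against 3 there are 10 splits, so the share of splits as large cannot go under 0.1, and in each comparison 1 split, the real one, gave a count as large. For genes the real and highest other counts were 2854 and 0 in RSL3 against DMSO, 1117 and 2 in RSL3 plus Fer-1 against RSL3, and 1157 and 2 in RSL3 plus Fer-1 against DMSO. For long noncoding RNAs they were 116 and 0, 63 and 1, and 56 and 0. For gene lists by camera they were 19 and 13, 16 and 13, and 14 and 8. Camera with the preset correlation thus called up to 13 lists in splits where 0 genes were called. Each other split still has unequal numbers of both groups on its sides, so some of these calls may come from the treatment. The list counts are therefore weaker evidence than the gene counts.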
